A study of Mus musculus with 5 samples.

How the data were processed

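Nuclear RNA was measured in 5 libraries of cardiomyocyte nuclei from infarcted hearts of FVB mice aged 8 weeks. Per the labels' protocols, the left anterior descending coronary artery was tied off permanently, and the heart was taken 7 days later. The border zone, the living muscle next to the infarct, and the remote myocardium, muscle away from it, were microdissected and frozen. Nuclei were stained with an antibody against PCM-1, a centrosomal protein that surrounds cardiomyocyte nuclei, and sorted by flow cytometry. The cDNA was made from 500 pg of input with a low-input amplification kit. The border zone group holds the libraries of mice 32, 34 and 40, and the remote group those of mice 40 and 43. The labels therefore name 4 animals, and only mouse 40 gave both regions.

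The deposited per-library table holds a never-negative signal, namely reads per gene divided by a size factor for each library. The submitters' processing notes name STAR, DESeq2 and the mm10 build, without versions or roles, and the counting tool and gene annotation are not given in the sources used here. In each library, 100% of the values above 0 were whole multiples of the smallest value, within 0.01, so the read numbers could be recovered. The size factors so obtained were 0.631, 0.813 and 1.28 for border zone mice 32, 34 and 40, and 1.32 and 1.37 for remote mice 40 and 43. DESeq2's own size factors, computed on the recovered reads, had the same values. The table lists 41128 genes, of which 13620 are at 0 in all libraries. Gene symbols came from the file for 21812 rows, and 18579 further rows were named by Ensembl ID from the reference gene names, which held 40254 of the IDs. A second table by the authors gives the longest transcript length of each gene, and its group means per kilobase were not used. The authors' deposited comparison table gives a log2 fold change, a p-value and an adjusted p-value per gene, and those values are quoted as the authors' own.

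Recovered depth was 25014205, 21042257 and 18725791 reads for border zone mice 32, 34 and 40, and 13440421 and 11324539 for remote mice 40 and 43. With 3 libraries against 2, the spread between libraries limits the precision of most comparisons. The p-values for single genes measure the spread between libraries within a region, with the 2 libraries of mouse 40 taken as independent.

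The main test, chosen before the data were examined, was limma 3.58.1 (R 4.3.3) on log2(value + 1) with a mean-variance trend and group as the only term. It was two-sided, used Benjamini-Hochberg adjusted p under 0.05, and ran on genes with a mean normalized value of at least 10. Fold changes are on the log2(value + 1) scale, on which genes with libraries near 0 can have smaller or larger changes than in the count models. No term for the animal was possible, since only mouse 40 contributed to both groups. Normalized values are given as mean ± SD, and log2 changes as border zone over remote ± SE. The count tests were edgeR 4.0.16 (quasi-likelihood, TMM) and DESeq2 1.42.0 (Wald) on the recovered reads.

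Gene lists fixed before the data were examined numbered 28. They covered stress and fetal genes, adult sarcomere genes, ion channels and connexins, calcium handling, fatty acid oxidation, oxidative phosphorylation, the citric acid cycle, branched-chain amino acid catabolism, mitochondrial regulators, glycolysis, AP-1 and immediate early genes, cardiac transcription factors, cytoskeleton and adhesion, TGF-beta and YAP targets, hypoxia, endoplasmic reticulum stress, interferon response, the cell cycle, mitochondrially encoded genes, cytoplasmic ribosomal proteins and sex-linked genes. Marker lists were included for fibroblasts, endothelium, macrophages, smooth muscle and pericytes, lymphocytes, mesothelium and adipocytes, as cell types that a sort of nuclei could let through. Lists were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. The preset correlation takes the genes of a list as nearly independent. List medians are given minus the median of all tested genes. Each list median was also set against 10000 random lists matched gene by gene on mean expression, transcript length and GC content, drawn from the 200 nearest genes. GC content came from the longest transcript in GENCODE M21, which had a value for 99.1% of tested genes. Coordinates are from the same annotation, whose assembly is that of mm10.

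The rule for named genes was also fixed beforehand. It took the 8 largest rises and 8 largest falls past the threshold with a mean of at least 100 and no overlap between groups, leaving out predicted genes and pseudogenes. It further took up to 4 passing members of each list, or the 2 with the highest mean where none passed, and a set of genes named in advance. As limma called no gene, the parts on passing genes were applied to the authors' deposited table, a step chosen after seeing the data. Genes singled out in other ways are said to be so, and not every gene that the rule took is described.

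Alternatives covered the pseudocount, the filter, the scaling, the weighting of libraries, the threshold, the test and the removal of each library. Ranges of adjusted p given for a list over the alternatives are those of camera at preset correlation. They leave out the weighting of libraries and filters at means of at least 500 and 5000. Alternatives added after seeing the data were total-count scaling, CPM (each library scaled to the same total), means of at least 500 and 5000, removal of GC content and abundance trends from each library with splines, DESeq2 without each library, and both tools without the border zone libraries of mice 32 and 34.

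The procedure was tested on counts simulated for the real genes, with 200 of them changed, in the same 3 and 2 libraries. Counts were drawn independently for each gene from its mean over all libraries. The simulation therefore held no correlation between genes, no GC content trend and no grouping of libraries other than by region. Its numbers of unchanged genes and lists called do not cover such structure. At the spread estimated from the data, limma tested 14735 genes and recovered 0 of 67 genes changed 2-fold, 2 of 67 changed 4-fold and 21 of 66 changed 8-fold, with 1 unchanged gene called. DESeq2 recovered 4 of 67, 13 of 67 and 44 of 66, with 73 unchanged genes called among 24514 with a p-value. edgeR recovered 0 at each fold size, with 1 unchanged gene called. Camera at preset correlation called the raised and the lowered simulated list, but also 1 of 2 unchanged lists (adjusted p = 0.0458, and 0.139 with an estimated correlation). At a low simulated spread limma recovered 64 of 67, 67 of 67 and 66 of 66.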

Results

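The series compared cardiomyocyte nuclei of the myocardial infarct border zone with those of remote myocardium, 7 days after coronary artery ligation in mice. Nuclear RNA was sequenced from 3 border zone samples (mice 32, 34 and 40) and 2 remote samples (mice 40 and 43). Nuclear RNA holds unspliced and retained transcripts, and Malat1, a nuclear long non-coding RNA, alone made up 15.8% to 25.9% of the reads of a library.

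The libraries differed in how many genes they held. At the depth of the shallowest library, 11324539 reads, 15843, 18288 and 19602 genes were expected in the border zone libraries of mice 32, 34 and 40, against 22670 and 22386 in the remote libraries of mice 40 and 43. The 10 most abundant genes took 60.3%, 55.5% and 45.6% of the border zone reads and 43.5% and 34.4% of the remote reads. Across the 14989 tested genes, the border zone library of mouse 40 correlated better with the remote library of the same animal (Pearson r = 0.842) than with border zone mouse 34 (r = 0.767) or mouse 32 (r = 0.733). With the remote library of mouse 43, another animal, border zone mouse 40 correlated at r = 0.772. The remote libraries of mice 40 and 43 correlated at r = 0.876. Genes are not independent replicates, so these r values describe the libraries only. The first principal component held 53.8% of the variance and placed border zone mice 32 and 34 on one side and the other 3 libraries on the other.

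**Figure D1:**
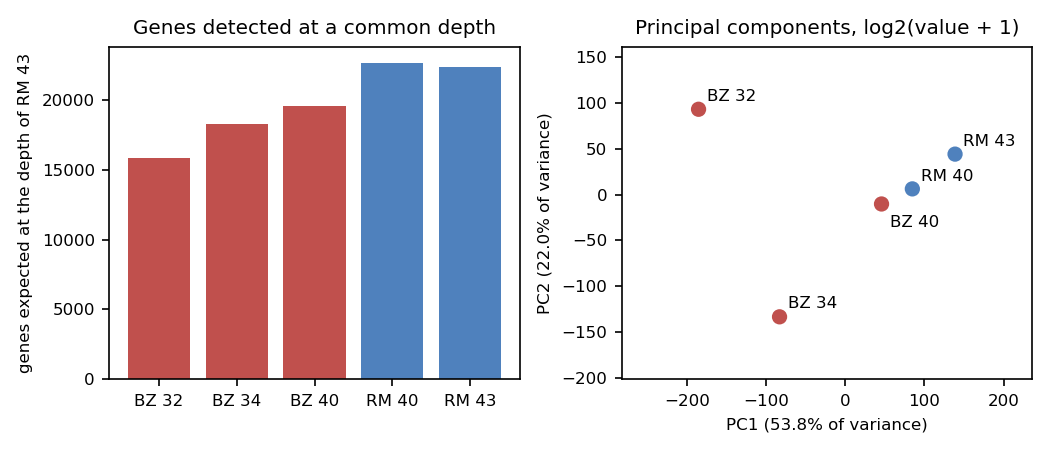
Left, genes expected in each library at the depth of the remote library of mouse 43, with border zone (BZ) in red and remote myocardium (RM) in blue. Right, the first 2 principal components of the log2 values, where each point is a library and border zone mouse 40 lies beside remote mouse 40; the 3 border zone libraries hold 15843 to 19602 genes and the 2 remote ones 22386 and 22670.

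The main question was which genes differ between border zone and remote cardiomyocytes. In the authors' deposited table, 574 genes were higher and 328 lower in the border zone at adjusted p under 0.05, of 16592 genes with an adjusted p. Among genes with a mean of at least 100 and no overlap between the groups' libraries, the largest rises in the authors' deposited table included Hspa1a, an inducible heat shock protein with a near-identical copy in Hspa1b (log2 4.99, adjusted p = 1.2e-05), and Tox2, a nuclear HMG-box protein (log2 5.65, adjusted p = 0.00031). The authors' deposited table also held the small nucleolar RNA gene Rnu3a (log2 6.97) and the 5.8S ribosomal RNA gene n-R5-8s1 (log2 5.04) among these. Rnu3a stood at 889 and 635 normalized reads in border zone mice 32 and 34, at 34.4 in border zone mouse 40, and at 7.55 and 0.731 in the remote libraries of mice 40 and 43. By the same rule the largest falls in the authors' deposited table were those of Mpc2, a subunit of the mitochondrial pyruvate carrier (log2 -4.93, adjusted p = 0.0048), and Ces1d, a carboxylesterase (log2 -4.55, adjusted p = 0.013). Next in the authors' deposited table came Glt28d2 (log2 -3.55), the mitochondrial ribosomal protein gene Mrpl15 (log2 -3.53), Pfkfb1, which sets the level of a glycolytic activator (log2 -3.52), Fam173b (log2 -3.33), Lgals4 (log2 -3.31) and Kcnv2, a modifier subunit of potassium channels (log2 -3.22).

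By limma, 0 of 14989 genes passed in either direction, and the smallest adjusted p was 0.133. At an unadjusted p under 0.05 limma gave 2708 genes, 1528 of them higher, where chance alone would give 749 on average. Of the other ways to part the libraries into 3 and 2, only a single parting gave more such genes. It set border zone mouse 40 and remote mice 40 and 43 against the remaining border zone libraries, and gave 4155. The rest gave 95 to 812. The excess over 749 was therefore not specific to the region. edgeR on the recovered reads also called 0 genes, with 2394 at an unadjusted p under 0.05. DESeq2 on the recovered reads called 902 genes, all of them among the authors' calls, in the same 574 and 328 directions. Of these, 894 were tested by limma, all with the same sign, and 848 had an unadjusted limma p under 0.05. The groups' libraries did not overlap for 847 of the 902, and for 39.2% of all tested genes, against the 20% that chance gives for 3 libraries against 2. Normalized values under 10 in at least 2 libraries were found for 303 of the 902, of which 196 were lower in the border zone.

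The number of calls depended on single libraries. Without border zone mouse 40, limma called 205 genes higher and 30 lower, and DESeq2 1477 and 1324. Without remote mouse 43, DESeq2 called 35 higher and 0 lower, and without remote mouse 40 it called 478 and 48. Without border zone mouse 32 it called 297 and 227, and without mouse 34 it called 251 and 207. Leaving out border zone mice 32 and 34, so that only mice 40 and 43 remained, DESeq2 called 120 higher and 208 lower, and 144 of these genes were among the 902. With border zone mice 32 and 34, the 2 libraries with the fewest genes at equal depth, against the 3 libraries of mice 40 and 43, DESeq2 called 2598 genes and limma 852. Total-count scaling moved the median log2 change of all tested genes from -0.21 to -1.58, a shift of -1.37, and quantile normalization moved it by 0.15, so list values are given relative to that median.

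**Figure D2:**
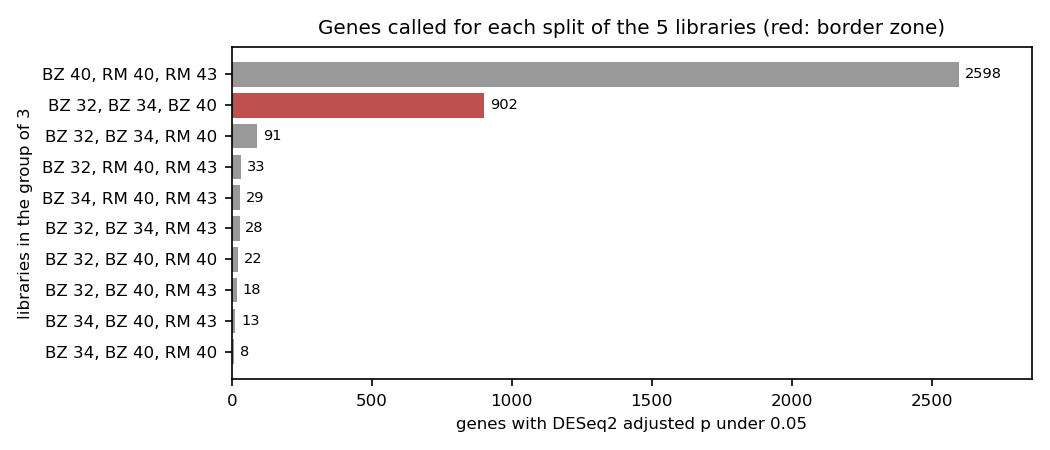
Genes called by DESeq2 for each of the 10 ways to part the 5 libraries into 3 and 2. The parting by region gives 902 calls, and the one that sets border zone mice 32 and 34 against the libraries of mice 40 and 43 gives 2598.

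Genes of cardiac stress stood higher in the border zone. Of the 18 tested stress and fetal genes, 16 had positive changes, and the list median lay 2.43 ± 0.46 (log2, bootstrap SE) above that of all genes (camera adjusted p = 3.14e-06). That call was lost with an estimated correlation (adjusted p = 0.501), and the median lay at 1.27 in the libraries of mice 40 and 43 alone and at 0.79 once GC content and abundance trends were removed. Adjusted over the list alone, 11 members passed by limma, all higher, and over all tested genes 0 did. The authors' deposited table called 9 members higher and 0 lower. Xirp2, an actin-binding protein of the intercalated disc (ENSMUSG00000027022, mm10 chromosome 2, 67446002 to 67526614, plus strand), had 312252 ± 240745 normalized reads (SD, n = 3) in the border zone and 27257 ± 13684 (SD, n = 2) in remote muscle, a log2 change of 3.26 ± 0.79. Cryab, a small heat shock protein (chromosome 9, 50751325 to 50756636, plus strand), had 9356 ± 5570 (SD, n = 3) and 1017 ± 248 (SD, n = 2), a log2 change of 2.97 ± 0.61. The intermediate filament gene Des (ENSMUSG00000026208, chromosome 1, 75360329 to 75368579, plus strand) had 24996 ± 13538 (SD, n = 3) and 3712 ± 1775 (SD, n = 2), a log2 change of 2.66 ± 0.60. Xirp1 had a log2 change of 2.59 ± 0.65. The limma adjusted p of these 4 genes lay at 0.133 to 0.14, while the authors' deposited table gave adjusted p of 0.0024 for Xirp2, 0.0023 for Cryab, 0.0089 for Des and 0.014 for Xirp1. The natriuretic peptide genes, classical markers of strain, did not pass by limma or in the authors' deposited table. Nppa had a log2 change of 1.30 ± 0.63 (limma adjusted p = 0.298) and Nppb of 0.94 ± 0.45 (limma adjusted p = 0.296). In normalized values all 3 border zone libraries lay above both remote ones for each gene. That direction depended on the scaling. With total-count scaling the changes were -0.12 for Nppa and -0.49 for Nppb, though both stayed above the median of all tested genes. Ankrd1, a titin-associated stress protein, had 1.80 ± 0.62 and Clu 0.68 ± 0.51 on the log2 scale, with limma adjusted p of 0.191 and 0.494.

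The contractile genes gave a direction that depended on the scaling. The adult sarcomere list (20 genes) lay 1.09 ± 0.29 above all genes (camera adjusted p = 0.00744, and adjusted p = 0.501 with an estimated correlation), but lay at -0.67 after quantile normalization and at -0.71 once GC content and abundance trends were removed. Camera then called the list lower (adjusted p = 0.0442 and 0.00756, within a range of 0.000635 to 0.317 over the alternatives), and in the libraries of mice 40 and 43 alone it did not pass (adjusted p = 0.317). Adjusted over the list alone 0 members passed by limma, and Tpm1, a thin filament tropomyosin, was called higher in the authors' deposited table (log2 2.24, adjusted p = 0.039). Myh6, the adult alpha myosin heavy chain, had 450177 ± 299620 normalized reads (SD, n = 3) in the border zone and 177345 ± 60404 (SD, n = 2) in remote muscle. Its log2 change was 1.14 ± 0.84, and within mouse 40 it was -0.32. Myh7, the fetal beta chain, gave 1.09 ± 0.70, and -0.11 within mouse 40, while Ttn gave 1.55 ± 1.15. Under quantile normalization the changes of Myh6, Myh7 and Ttn were -1.32, -1.18 and -0.62. Among the channel and connexin genes, the authors' deposited table called Kcnv2 lower (adjusted p = 0.016). Neither that list (camera adjusted p = 0.881) nor calcium handling (camera adjusted p = 0.283) passed. Adjusted over each list alone, 2 channel and connexin members passed by limma, both higher, and 1 calcium handling member, which was lower. Among calcium handling genes, the ryanodine receptor gene Ryr2 gave 0.84 ± 0.59, negative under quantile normalization, and the calcium pump gene Atp2a2 -0.91 ± 0.52 on the log2 scale, neither past the threshold.

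**Figure D3:**
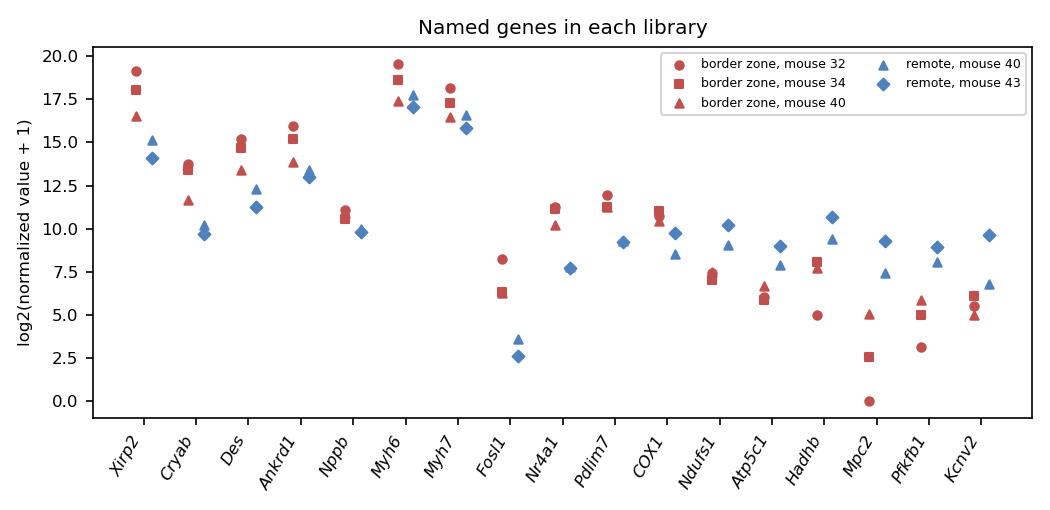
Normalized values of 17 named genes as log2(value + 1), where each point is a library, red marks border zone and blue remote myocardium, and the symbol shape gives the mouse. For Des the 3 border zone points lie above both remote points, while for Myh6 the border zone library of mouse 40 lies below the remote library of the same animal.

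Genes of mitochondrial metabolism encoded in the nucleus stood lower in the border zone. The oxidative phosphorylation list lay -1.65 ± 0.23 from all genes, with 26 of 27 members negative (camera adjusted p = 2.57e-05, and adjusted p = 0.501 with an estimated correlation). The citric acid cycle list lay at -1.22 ± 0.36, with 16 of 17 negative (camera adjusted p = 0.00285, and adjusted p = 0.501 with an estimated correlation). Fatty acid oxidation genes lay at -0.77 ± 0.28, with 19 of 24 negative (camera adjusted p = 0.0216, and adjusted p = 0.501 with an estimated correlation). Without 1 library the fatty acid median ran from -0.52 to -1.23. Branched-chain amino acid catabolism lay at -0.75 ± 0.46, with 14 of 16 negative (camera adjusted p = 0.0414, and adjusted p = 0.501 with an estimated correlation). Its median ran from -0.60 to -1.15 without 1 library. Adjusted over each of these 4 lists alone, 0 members passed by limma. The oxidative phosphorylation call held without each library, with a median of -0.98 without remote mouse 43, whereas the fatty acid list did not pass without border zone mouse 34, border zone mouse 40 or remote mouse 43 (adjusted p = 0.0698, 0.0701 and 0.234, within a range of 0.00057 to 0.234 over the alternatives). The branched-chain amino acid list did not pass without border zone mouse 34 or remote mouse 43 (adjusted p = 0.111 and 0.103, within a range of 0.00446 to 0.333 over the alternatives). In the libraries of mice 40 and 43 alone oxidative phosphorylation lay at -0.93 and still passed, while the citric acid cycle, fatty acid and branched-chain amino acid lists lay at -0.85, -0.77 and -0.62 and did not. Ndufs1, the largest core subunit of respiratory complex I (ENSMUSG00000025968, chromosome 1, 63143596 to 63176833, minus strand), had 160 ± 27.1 normalized reads (SD, n = 3) in the border zone and 853 ± 456 (SD, n = 2) in remote muscle, a log2 change of -2.31 ± 0.59. Atp5c1, a subunit of the ATP synthase, had 74.4 ± 24 (SD, n = 3) and 377 ± 194 (SD, n = 2), a log2 change of -2.27 ± 0.70. Hadhb, of the mitochondrial trifunctional protein, had 171 ± 123 (SD, n = 3) and 1152 ± 675 (SD, n = 2), a log2 change of -3.09 ± 0.86. These were the only members of the 4 lists called in the authors' deposited table, with adjusted p of 0.011 for Ndufs1, 0.027 for Atp5c1 and 0.043 for Hadhb. Atp5b (-2.05 ± 0.71), Lpl (-1.15 ± 0.52) and Mccc1 (-1.49 ± 0.54) are given as abundant members that did not pass, and the Atp5b change was 0.04 within mouse 40. All 4 lists stayed negative under each alternative run, and in mouse 40 alone the oxidative phosphorylation list lay at -0.42. The list of mitochondrial regulators did not pass (camera adjusted p = 0.159). Its coactivator genes Ppargc1a and Ppargc1b gave log2 changes of -0.74 ± 0.47 and 1.87 ± 0.55. The glycolysis list did not pass either (camera adjusted p = 0.639), although its median lay at percentile 0.01 of random lists matched on expression, length and GC content. Its member Pfkfb1 was called lower in the authors' deposited table (adjusted p = 0.0057).

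The genes encoded in the mitochondrial DNA went the other way. All 9 had positive changes, and their median lay 1.37 ± 0.16 above all genes (camera adjusted p = 0.00349, and adjusted p = 0.501 with an estimated correlation). As a share of reads, mitochondrially encoded messenger RNAs together made up 0.0132%, 0.0230% and 0.0259% in border zone mice 32, 34 and 40. In remote mice 40 and 43 they made up 0.0134% and 0.0346%. The rise of these messenger RNAs was thus relative to the other tested genes and not a rise in read share. Mitochondrially encoded ribosomal RNAs, which are not on the list, made up 1.26%, 2.42% and 2.22% of reads in border zone mice 32, 34 and 40. Their share was 0.997% and 0.919% in remote mice 40 and 43. COX1, a subunit of cytochrome oxidase, had 1714 ± 340 normalized reads (SD, n = 3) in the border zone and 627 ± 359 (SD, n = 2) in remote muscle. Adjusted over this list alone, 0 members passed by limma, and without remote mouse 40 the list lay at 0.78 and did not pass.

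**Figure D4:**
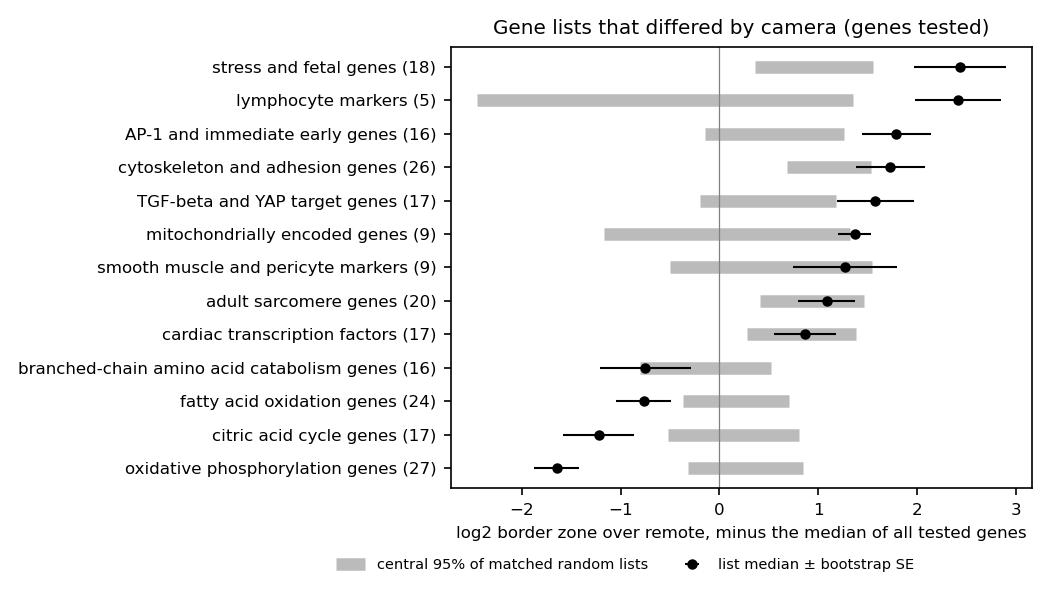
Median log2 change of each of the 13 lists that passed camera at preset correlation, minus the median of all tested genes, with bootstrap SE over members as bars and the number of genes tested in brackets. Grey bands hold the central 95% of random lists matched on expression, length and GC content; the oxidative phosphorylation point at -1.65 lies outside its band, while the adult sarcomere point at 1.09, which turns negative under quantile normalization, lies inside.

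Transcription factor genes of the immediate early response stood higher. The AP-1 and immediate early list lay 1.79 ± 0.35 above all genes, and 0.96 above them in the libraries of mice 40 and 43 alone, with 15 of 16 tested members positive (camera adjusted p = 2.57e-05, and adjusted p = 0.501 with an estimated correlation). Adjusted over the list alone, 4 members passed by limma, and the authors' deposited table called 4 higher and 0 lower. Fosl1, an AP-1 subunit (chromosome 19, 5447547 to 5455946, plus strand), had 154 ± 133 normalized reads (SD, n = 3) in the border zone and 8.22 ± 4.39 (SD, n = 2) in remote muscle, a log2 change of 3.83 ± 1.05. Nr4a1, an orphan nuclear receptor (ENSMUSG00000023034, chromosome 15, 101254269 to 101274795, plus strand), had 1982 ± 678 (SD, n = 3) and 216 ± 5.99 (SD, n = 2), a log2 change of 3.12 ± 0.51. The authors' deposited table gave adjusted p of 0.0021 for Fosl1, 0.00015 for Nr4a1, 0.0051 for Myc and 0.012 for Junb. Of the other AP-1 genes named in advance, log2 changes were 1.28 ± 0.47 for Fosl2, 1.56 ± 0.58 for Jun, 1.03 ± 0.85 for Jund, 2.05 ± 1.11 for Atf3 and 0.45 ± 1.38 for Fos, which averaged 12.9 ± 5.44 normalized reads (SD, n = 3) in the border zone. None of these 5 passed by limma or in the authors' deposited table, and Jund was at -0.72 within mouse 40. Runx1 gave 0.91 ± 0.69.

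Cardiac transcription factors lay 0.87 ± 0.31 above all genes (camera adjusted p = 0.00744, and adjusted p = 0.501 with an estimated correlation), a call that was lost after quantile normalization (adjusted p = 0.523, within a range of 0.000487 to 0.919 over the alternatives). Without 1 library the list median ran from 0.57 to 1.22. Adjusted over the list alone 3 of its 17 members passed by limma. The authors' deposited table called Srf, the serum response factor (log2 2.67, adjusted p = 0.016), and Prdm16 (log2 2.12, adjusted p = 0.024) higher. The MEF2 genes, which encode muscle transcription factors, gave -1.24 ± 0.53 for Mef2a, 0.05 ± 0.53 for Mef2c and 1.47 ± 0.46 for Mef2d, and none passed by limma or in the authors' deposited table.

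Cytoskeletal and TGF-beta response genes also stood higher. The cytoskeleton and adhesion list lay 1.73 ± 0.35 above all genes, with 22 of 26 positive (camera adjusted p = 3.14e-06, and adjusted p = 0.501 with an estimated correlation). Adjusted over the list alone 14 members passed by limma, and the authors' deposited table called 9 higher. Des and Flnc stood on this list and on the stress list. Once GC content and abundance trends were removed, its median was 0.56 and camera gave an adjusted p of 0.103. That was the highest over the alternatives at preset correlation, whose lowest was 5.95e-08. In the libraries of mice 40 and 43 alone the list lay at 0.94 and passed. The log2 changes were 3.37 ± 0.79 for the non-muscle myosin gene Myh9, 3.03 ± 0.67 for Actn4, 2.54 ± 0.55 for the fibronectin receptor subunit gene Itga5 and 2.23 ± 0.46 for Pdlim7. Their adjusted p in the authors' deposited table were 0.0062, 0.0086, 0.0083 and 0.0059. The TGF-beta and YAP target list lay 1.58 ± 0.39 above all genes, with 13 of 17 positive (camera adjusted p = 0.00285, and adjusted p = 0.501 with an estimated correlation). Adjusted over the list alone 8 members passed by limma, and in the libraries of mice 40 and 43 alone the list lay at 1.17 and did not pass. Its median was 0.79 once GC content and abundance trends were removed. The authors' deposited table called Smad7, an inhibitor of TGF-beta signalling, higher (log2 1.91, adjusted p = 0.041).

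Markers of other cell types moved in different directions. Smooth muscle and pericyte markers lay 1.27 ± 0.52 above all genes (camera adjusted p = 0.0472, and adjusted p = 0.501 with an estimated correlation), led by Cspg4, with 8635 ± 3047 normalized reads (SD, n = 3) in the border zone and 1025 ± 1025 (SD, n = 2) in remote muscle. Adjusted over that list alone, 3 members passed by limma, 2 higher and 1 lower. Lymphocyte markers lay 2.41 ± 0.44 above all genes (camera adjusted p = 0.0154, and adjusted p = 0.501 with an estimated correlation), over 5 tested genes with few reads. Without 1 library the lymphocyte median ran from 2.06 to 3.89. Cd3d, a T cell receptor component, stood at 185, 62.8 and 3.13 in border zone mice 32, 34 and 40 and at 5.28 and 0.731 in the remote libraries of mice 40 and 43, and the list lay at -0.02 in mouse 40 alone. Without border zone mouse 34 the lymphocyte list did not pass (adjusted p = 0.0765, within a range of 7.31e-05 to 0.811 over the alternatives), and the smooth muscle list did not pass without border zone mice 32, 34 or 40 or remote mouse 43 (adjusted p = 0.0866, 0.0765, 0.061 and 0.103, within a range of 0.038 to 0.505). The authors' deposited table called 2 macrophage markers lower, Mrc1 (log2 -4.10, adjusted p = 0.023) and C1qc (log2 -3.48, adjusted p = 0.034), and called Fn1, on the fibroblast list, higher (log2 1.93, adjusted p = 0.042). Fibroblast (camera adjusted p = 0.4), endothelial (camera adjusted p = 0.731), macrophage (camera adjusted p = 0.159) and mesothelial (camera adjusted p = 0.112) markers did not pass as lists, and a single adipocyte marker was abundant enough to test. Col1a1, a fibroblast collagen, had 2182 ± 981 normalized reads (SD, n = 3) in the border zone and 716 ± 259 (SD, n = 2) in remote muscle. Pcm1, the gene of the protein used for sorting, had 501 ± 123 (SD, n = 3) and 872 ± 94 (SD, n = 2), a log2 change of -0.82 ± 0.50 that did not pass by limma and was 0.12 once the GC content trend was removed.

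The other lists did not pass camera. Their adjusted p were 0.978 for hypoxia, 0.477 for endoplasmic reticulum stress, 0.46 for interferon response, 0.89 for the cell cycle, 0.101 for cytoplasmic ribosomal proteins and 0.266 for sex-linked genes. Of the 27 lists tested, 9 stood higher and 4 lower by camera at preset correlation, while 0 passed with an estimated correlation and 0 with fry, whose smallest adjusted p was 0.151. In the libraries of mice 40 and 43 alone, 5 lists passed, of which 4 were among the 13, namely the stress, AP-1, cytoskeleton and oxidative phosphorylation lists, and the other was that of mesothelial markers with 2 tested genes (adjusted p = 0.0435).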

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

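Alternatives chosen after the data were seen were total-count scaling, CPM, means of at least 500 and 5000, the removal of GC content or abundance trends, the libraries of mice 40 and 43 alone, and for DESeq2 other thresholds and filters and the removal of each library. limma called 0 genes, against 2708 at an unadjusted p under 0.05 and 902 by DESeq2. It called 1035 higher and 698 lower with library weights, and 1 higher with quantile normalization or total-count scaling. It called 34 higher and 1104 lower with CPM, 288 and 14 at means of at least 500, and 111 higher at means of at least 5000. DESeq2 and the authors' deposited table gave 574 and 328, and DESeq2 gave 187 and 87 at adjusted p under 0.01 and 120 and 208 in mice 40 and 43 alone. Leaving out 1 library gave limma 0 to 205 higher and 0 to 30 lower, and DESeq2 35 to 1477 and 0 to 1324, where a group left with 1 library was assumed to vary like the other. Of 27 lists, 13 passed camera, 10 to 13 without 1 library, 8 at means of at least 500, 5 in mice 40 and 43 alone, and 0 with an estimated correlation or fry. A tally over the lists left out library weights, CPM, means of at least 500 and 5000, and the tests with an estimated correlation or fry. In it, 172 alternatives with a camera test kept direction and call and 33 kept direction only, and 52 without that test kept direction. The other 3 reversed: adult sarcomere genes at -0.67 with quantile normalization and -0.71 with GC content and abundance trends removed, and lymphocyte markers at -0.0199 in mouse 40 alone. Total-count scaling shifted the median of all genes by -1.37 and so turned the sign of Nppa (-0.12), Nppb (-0.49), Myh6 (-0.29), Myh7 (-0.34), Clu (-0.75), Ryr2 (-0.59), Mef2c (-1.38), Fos (-0.86), Fosl2 (-0.15), Jund (-0.38) and Runx1 (-0.51), all 11 of which stayed above that median. Genes reversed with quantile normalization were Myh6 (-1.32), Myh7 (-1.18), Ryr2 (-1.18), Mef2c (-0.32) and Ttn (-0.62), and with TMM and upper-quartile scaling Mef2c (-0.00984 and -0.13), which also stayed above the median. With GC content and abundance trends removed they were Myh6 (-1.45), Myh7 (-1.34), Clu (-0.41), Ryr2 (-0.88), Mef2d (-0.17), Jund (-0.17) and Ttn (-0.55), and with GC content alone Ppargc1a (0.19), Jund (-0.11) and Pcm1 (0.12). In mouse 40 alone they were Myh6 (-0.32), Myh7 (-0.11), Jund (-0.72), Atp5b (0.0378) and Cd3d (-0.61), and in mice 40 and 43 alone Fos (-0.00999) and Jund (-0.38). Without 1 library Mef2c ranged from -0.18 to 0.35 and Fos from -0.17 to 1.08. Higher mean thresholds leave fewer genes to test, and for the other alternatives the cause was not tested. No paired analysis was possible because only mouse 40 gave both regions, and a random effect for the mouse could not be fitted for any of 14989 genes.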

Other observations

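Tests chosen only after the result was seen were those of abundance measured on the same libraries, of lists matched on GC content or with trends removed, of the share of cardiomyocyte nuclei, of the libraries of mice 40 and 43 alone, and of the mitochondrial ribosomal protein genes, and the gene families and smallest-p genes below were likewise chosen afterwards. Mitochondrial ribosomal protein genes, 71 of which were tested, had a median log2 change of -1.44, which lay at percentile 0.01 of random lists matched on abundance and transcript length. The whole family of respiratory complex I subunits (41 tested) had a median log2 change of -1.46, and the authors' deposited table called 3 members of each family lower. Unlike the list medians, these family values are not taken minus the median of all tested genes. Minus that median, the mitochondrial ribosomal family lay at -1.23 and the complex I family at -1.25. All 5 tested U3 small nucleolar RNA genes, which guide ribosomal RNA processing, were called higher in the authors' deposited table, with a median limma log2 change of 4.38. Rnu3b2 and Rnu3b4 had identical values in every library, so copies may share reads, which was not tested. Mice 32 and 34 carried that change, as Rnu3b1 stood at 596 and 679 normalized reads there, at 14.1 in border zone mouse 40, and at 6.79 and 8.04 in the remote libraries. Among the genes with the smallest limma p were Lif, Irs2 and Ahnak2, whose log2 changes in the authors' deposited table were 4.37, 3.41 and 3.68. Gm42418, which overlaps ribosomal RNA sequence, held 13.0%, 11.1% and 5.44% of the reads of border zone mice 32, 34 and 40 and 0.698% and 3.89% of those of remote mice 40 and 43. Lars2 held 2.96%, 2.06% and 1.33%, and 0.199% and 1.17%. Xist, expressed from the inactive X chromosome, stood at 193 to 572 normalized reads and the Y-linked gene Uty at 337 to 793 across the 5 libraries, so each held transcripts of both. The labels give 1 mouse number per library, and the comparisons by animal and the group sizes of 3 and 2 assume that each library held nuclei of that mouse alone, which was not tested.

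Abundant genes had higher changes than scarce genes, with a Spearman rho across genes of 0.356, where genes are not independent replicates. Fewer captured RNA molecules stay open, since the ratio of border zone mouse 32 to mouse 40, a single pair of libraries, had a rho of 0.0252 with the remote mean, below the 0.1 set for it, while genes at a remote mean of 50 to 200 were at 0 in 6.23%, 2.16% and 0.489% of cases in border zone mice 32, 34 and 40 and in 0% and 0.0407% in the remote libraries. Much of the trend may come from measuring abundance on the libraries that form the change, since with abundance from the other remote library the larger rho was 0.116. GC content could also contribute, as its rho with the change was 0.322 and that between border zone mice 32 and 40 was 0.167. The region itself cannot be told apart from fewer molecules, with a rho of 0.0690 within mouse 40, because no border zone library held as many genes as a remote one.

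Among random lists matched on abundance and transcript length, the oxidative phosphorylation, citric acid cycle and fatty acid lists lay at percentiles 0, 0 and 0.05, and with GC content matched too at 0, 0 and 0.04, while the stress, AP-1, cytoskeleton and TGF-beta lists lay at 100, 99.96, 99.72 and 99.91. This argues against these trends as the whole cause except for the cytoskeleton list, which stays open, as removing GC content and abundance trends lowered its median from 1.73 ± 0.35 to 0.56 ± 0.24 and so ended its call (adjusted p = 0.103), while the stress list went from 2.43 ± 0.46 to 0.79 ± 0.25 and still passed (adjusted p = 0.0195). For the cardiac transcription factor and adult sarcomere lists, at percentiles 55.9 and 68.8, the trends stay open. Matching and trend removal used abundance from the same libraries as the change, so they can also absorb a real change. Once the trends were removed, these lists lay at 0.15 and -0.71. The trends also stay open for the smooth muscle and branched-chain amino acid lists, at 90.4 and 3.65. Their medians were 1.44 ± 0.54 and -0.78 ± 0.26 once the trends were removed. The lymphocyte and mitochondrially encoded lists lay at 99.8 and 98.1. Fewer cardiomyocyte nuclei as the whole cause of the oxidative phosphorylation change was argued against by sarcomere genes. They stood above those genes by at least 0.683 log2 in all 6 library pairs, which share the 5 libraries. Once GC content and abundance trends were removed the gap was 1.01 ± 0.35, an SE over list members without the spread between animals. A part stays open, since the sarcomere list then lay at -0.71 and smooth muscle and lymphocyte markers stood higher. Pcm1 went from -0.82 to 0.12 with the GC content trend removed and to -0.63 with both trends removed. A difference between mice 32 and 34 and mice 40 and 43 cannot be told apart from the region for the full size of these changes, as with mice 40 and 43 alone the stress, AP-1, cytoskeleton and oxidative phosphorylation lists still passed (largest adjusted p = 0.0126), but on 1 border zone library.

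The border zone library of mouse 40 resembled the remote library of the same mouse more than it resembled the other border zone libraries. Among genes with a mean of at least 1000 the Pearson r was 0.901, against 0.775 for the closest border zone library, a gap of 0.126. Scarce molecules in mice 32 and 34 stay open as a cause, since that mean included the libraries of these mice. Genes high only there could pass and lower their correlation with border zone mouse 40. Over the same abundant genes border zone mouse 40 correlated with the remote library of mouse 43, another animal, at r = 0.782. That was close to its r of 0.775 with border zone mouse 34, and by Spearman rho the order was the opposite (0.658 and 0.661). These values therefore do not show a closer resemblance to the remote library of another animal than to a border zone library. Whether a shared animal contributes stays open. Over these abundant genes remote mouse 40 correlated better with border zone mouse 40 than with remote mouse 43 by 0.0392, but over all tested genes the order was the opposite (r = 0.842 and 0.876).

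The 10 splits of the 5 libraries are too few for a share under 0.05. The real split gave 902 DESeq2 calls, and 2 splits, the real one included, gave at least that many. The highest other was 2598, for border zone mice 32 and 34 against the libraries of mice 40 and 43, which points to a structure of the samples. This split follows both the animals and the 2 libraries with the fewest genes. It also parts border zone mice 32 and 34 from both remote libraries, so the region may contribute. No test of these calls separates these readings. Within mice 40 and 43, with 1 border zone library against 2 remote ones, DESeq2 called 328 genes, 144 of them among the 902.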
